A study of Homo sapiens with 8 samples.

How the data were processed

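Gene expression was measured in LS174T cells on 8 arrays of an Affymetrix human design whose probe sets carry perfect-match probes. Per the labels, cells were transduced with a doxycycline-inducible hairpin against GATA6 or a non-silencing one, RNA was extracted with a phenol-based kit, and cDNA was made and amplified with a whole-transcriptome kit, fragmented by DNase and biotinylated. The deposited values are log2 signals summarised by RMA, per the submitters' processing notes; the RMA version and probe annotation build are not given in the sources used here. RMA subtracts a background, equalises the distributions of arrays and fits 1 value per probe set, so total signal differences between arrays are not kept and low signals are compressed toward a floor. The values ran from 1.56 to 12.7. An arm in the series description that blocks beta-catenin/TCF activity was not analysed here.

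Groups and replicate numbers came from the sample titles. The series calls the samples biological replicates and does not say how cultures were separated, so p-values measure the spread between these samples, part of which may be technical. The table holds 54715 probe sets. Of these 40920 have 1 gene symbol in the array annotation given for the series, 864 have several and 12931 are not listed in it; only those with 1 symbol were named. Symbols were set against RefSeq genes of assembly GRCh38.p14 by gene ID for 40864 probe sets, and 0 differed. Each gene was represented by the probe set of highest mean over the 8 arrays, which gave 19774 genes; of 27 genes called with the block that have over 1 probe set, 5 have another that moved the opposite way, 0 of them at an unadjusted p under 0.05 by limma with the block. No dim gene was removed. No coordinates are given, since the array values name no genome build.

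Tests used R 4.3.3 and limma 3.58.1. A cell-means model of the 4 groups was fitted to all 8 arrays (lmFit, eBayes), with contrasts for the shGATA6 response, its difference from the non-silencing response, the non-silencing response and the vehicle baseline. It has 4 residual degrees of freedom, all from the shGATA6 arrays; the lone non-silencing arrays are assumed to vary like them. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. This design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined, except where the text says otherwise. An exact two-sided permutation test was used for GATA6. Camera, with a preset correlation of 0.01, tested 30 gene lists holding 626 genes, of which 574 were measured; the other members were not analysed here. Camera with an estimated correlation and fry were run beside it. The former has only the residual degrees of freedom, 4 without the block, 2 with it and 3 with the batch term described below. Over 30 lists it can then hardly pass, so a failure cannot tell whether correlation between genes made a call. Fry's directional p called 0 lists with the block or without it (camera called 4 and 1). Fry's mixed p ignores direction. With the block it was under 0.05 for some lists, such as stem cell genes (0.00248), and not others, such as cell cycle genes (0.373). The median and camera's direction differed in sign for several uncalled lists, among them BMP ligands, goblet, Paneth, stress and MAPK/ERK genes.

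A fit with the replicate number of the shGATA6 arrays as a block (the non-silencing pair as a block of its own) was an alternative fixed in advance. Whether the numbers pair the samples was judged by a fixed criterion, a correlation over 0.1 of the deviations of same-numbered arrays from their group means; the correlations were 0.386, 0.471 and 0.701, and 4 of the 6 arrays correlated best with their own number. The correlations and the numbers of calls came from one run. The pairing comes from replicate 3, which stands apart in both treatments: the difference of replicates 1 and 2 correlated at -0.04 between vehicle and doxycycline. The block leaves 2 residual degrees of freedom. The design is balanced, so both fits give the same fold changes and differ in error. A term for 2 batches, replicates 1 and 2 against all other arrays, was added after seeing the data; the labels name no batch.

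Named genes were GATA6, up to 4 called members of each list (or the 2 largest as values), the 12 largest changes each way among called genes whose treated and untreated arrays do not overlap, and the 5 largest each way for the other contrasts. The 12 were limited to genes whose higher group mean was above the median of gene means. The 5 were limited to genes whose mean over all arrays was above it. Where fewer passed, the 5 of smallest p were taken as values, without that limit, for the difference between hairpins. Without the block no gene passed, so the rule was applied to the calls of the blocked fit, with the same direction in all 3 pairs in place of no overlap, a change made after seeing the data. Sex-linked marker genes were left out of the text. Some members that the blocked fit called adjusted over the list alone were also named.

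The fits were tested on simulated data for all 19774 genes with 200 changed, 50 at each size. Each simulated array was the observed mean of its pair plus noise of the size left by the blocked fit. Pairing was thus built in, which favours the block, so the shares do not show that the block suits the real arrays. For the shGATA6 response, 0%, 34%, 94% and 96% of changes of 0.5, 1, 2 and 3 log2 were recovered without the block, 52%, 100%, 100% and 100% with it, and 12%, 98%, 100% and 100% with the batch term. Over 20 simulations 0%, 9.01% and 1.15% of the calls for this response were false without the block, with it and with the batch term, so the block exceeds the nominal 5%. With no gene changed the block called 0.6 genes on average and at most 4. For the difference between hairpins the shares were 0%, 0%, 34% and 84% without the block and 2%, 60%, 100% and 100% with it. Of 30 lists, 1 shifted by 0.5 was recovered in both fits, with 0 other lists called without the block and 1 with it. The simulated noise was drawn independently for each gene. It therefore cannot show how often correlation between genes gives false list calls. The shares of false gene calls, and the counts with no gene changed, likewise hold for uncorrelated genes only. Other settings tried were quantile normalization, median centring, filters on dim genes, the mean of a gene's probe sets or every probe set, the shGATA6 arrays alone, trend and robust priors, array weights, stricter thresholds, and leaving out each array or pair. Arrays have no read depth; their number and the signal floor limit precision.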

Results

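LS174T is a human colorectal cancer cell line. Its cells carried a doxycycline-inducible hairpin against the zinc-finger transcription factor GATA6 (shGATA6) or a non-silencing hairpin. They were treated for 72 h with 1 µg per mL doxycycline or with vehicle, which the labels give as 70% ethanol. Total RNA was profiled on 8 human Affymetrix arrays: 3 of shGATA6 cells with vehicle, 3 of shGATA6 cells with doxycycline, and 1 of non-silencing cells with each. The question named by the series is which genes respond to loss of GATA6. The values were log2 RMA signals, with array medians from 3.64 to 3.72, and 19774 genes were tested; the small number of arrays limits the precision.

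The targeted transcript was lower with doxycycline in every shGATA6 pair of the same replicate number. One of its 2 probe sets read 7.41 ± 0.29 with vehicle and 5.92 ± 0.56 with doxycycline (log2, mean ± SD, n = 3 each), which leaves 35.5% of the signal. The other, which has the higher mean and represents the gene in the tests below, read 7.33 ± 0.16 and 6.15 ± 0.53, which leaves 44.1%. In the non-silencing pair the same probe sets differed by -0.04 and 0.21. The 3 doxycycline arrays lay below the 3 vehicle arrays for both probe sets, and the two-sided exact permutation test gave p = 0.1, the smallest value it can give for 3 arrays against 3. By limma without a block neither probe set passed (adjusted p = 1.00 for both). With the replicate number as a block the adjusted p over all probe sets was 0.0241 for the former and 0.166 for the latter, and over genes 0.0624 for GATA6.

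**Figure D1:**
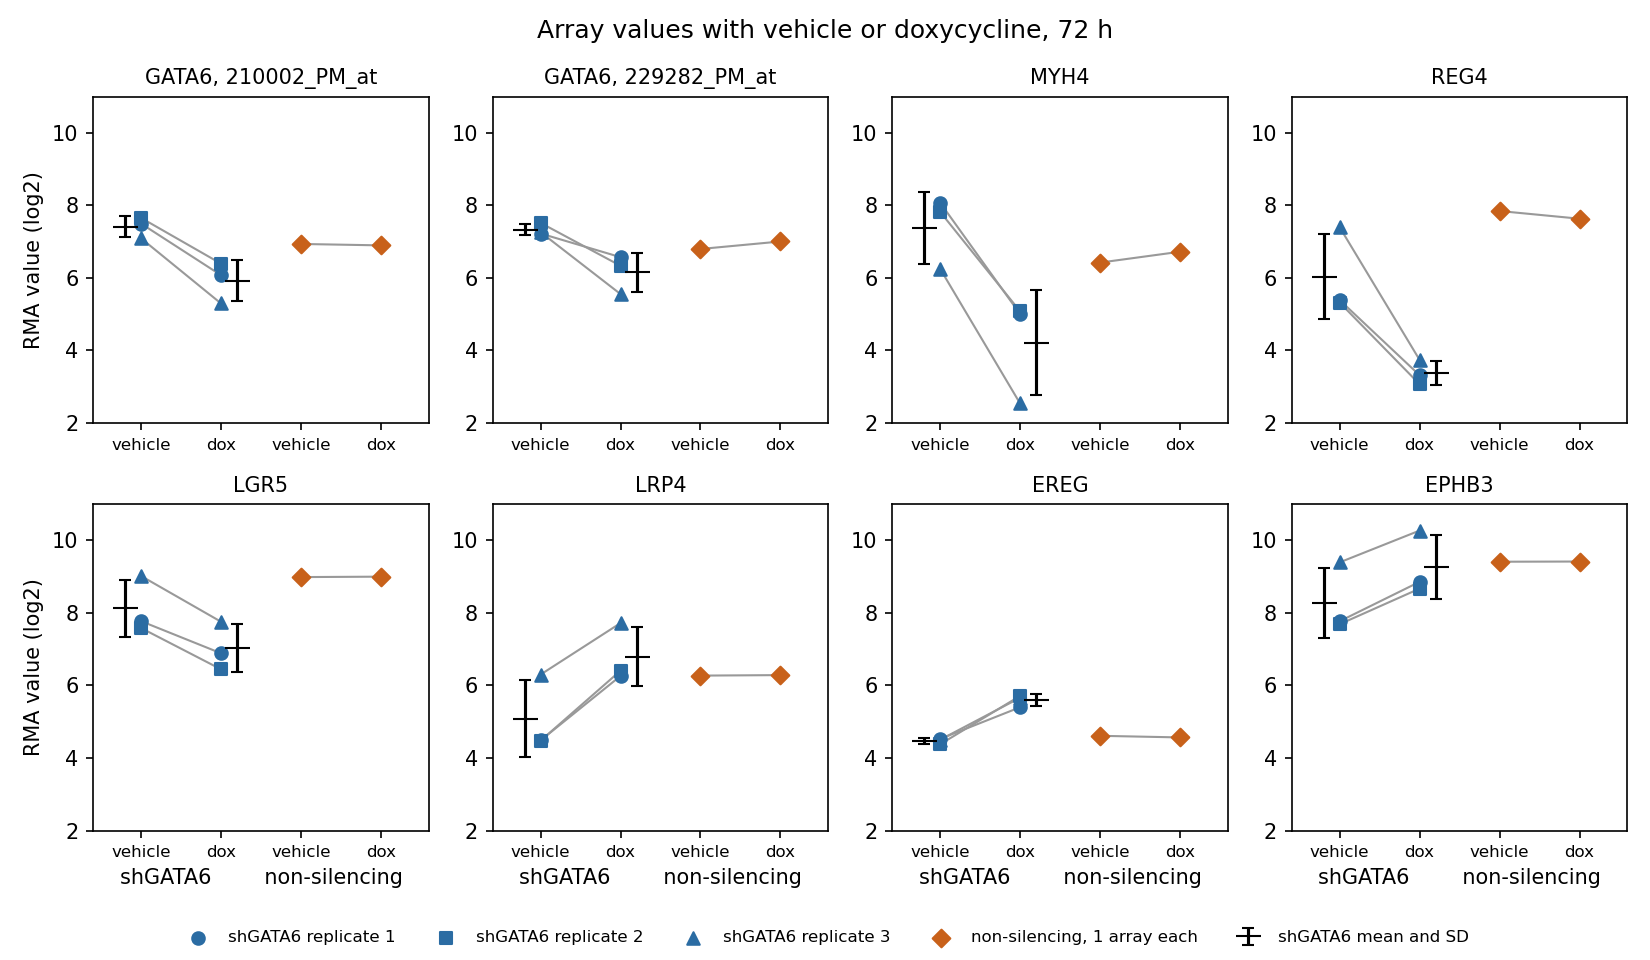
RMA values (log2, vertical axis) of GATA6 and 6 further genes on each of the 8 arrays, by hairpin and treatment (horizontal axis); blue symbols are the 3 shGATA6 replicates, grey lines join arrays of one replicate number or the non-silencing pair (orange diamonds), and black bars are the shGATA6 mean and SD. MYH4, REG4 and LGR5 are lower with doxycycline in all 3 shGATA6 pairs and LRP4, EREG and EPHB3 higher, while for MYH4, LGR5, LRP4 and EPHB3 replicate 3 lies apart from replicates 1 and 2 in both treatments, and for REG4 with vehicle.

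A skeletal muscle myosin pair, a secretory lectin and a stem cell receptor fell with doxycycline in shGATA6 cells, as tested by limma with the replicate number as a block; without the block no gene passed. MYH4 fell 9.03-fold (log2 -3.17 ± 0.18, SE, n = 3 pairs), and its relative in the same gene cluster, MYH13, fell 5.67-fold (-2.50 ± 0.19). REG4, a lectin secreted by gut secretory cells, fell 6.33-fold (-2.66 ± 0.26). These 3 folds are lower limits, since REG4 read 3.37 on average with doxycycline and MYH4 and MYH13 read 2.54 and 2.90 on doxycycline replicate 3, near the signal floor. LGR5, the R-spondin receptor that marks intestinal stem cells, fell 2.14-fold (-1.09 ± 0.13, adjusted p = 0.0175). UST, a sulfotransferase of glycosaminoglycan chains, fell 3.11-fold, NAV3 2.91-fold, and ALDH1A1, a retinaldehyde dehydrogenase, 2.84-fold. The glutathione transferases GSTM4 (2.65-fold) and GSTM1 (2.40-fold), and ZNF169 (2.56-fold), SAMD5 (2.41-fold) and GASK1B (2.31-fold, to a dim 3.57) fell as well. The MYH and GSTM genes each lie beside close relatives whose probes may share targets, so their separate folds are uncertain.

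The genes that rose in the same test numbered 15. LRP4, a receptor of the LDL receptor family, rose most (3.27-fold, log2 1.71 ± 0.14, SE, n = 3 pairs, adjusted p = 0.00236), followed by TOX3, an HMG-box nuclear protein (2.59-fold, 1.37 ± 0.13). EREG, a ligand of the EGF receptor, rose from 4.47 ± 0.08 to 5.59 ± 0.17 (SD, 2.18-fold), and its non-silencing difference was -0.04. EPHB3, an ephrin receptor of the crypt base, rose 1.98-fold (0.98 ± 0.12), NT5E, an ecto-nucleotidase, 2.19-fold, and MFSD2A, a lipid transporter, 2.46-fold. GPR15LG rose 2.56-fold (from a dim 3.58), CADPS 2.54-fold, ASB4 2.41-fold and FAIM2 1.98-fold. The ASB4 fold is a lower limit, since its vehicle replicates 1 and 2 read 3.17 and 2.95, near the signal floor. CD24 rose 2.22-fold and PDE4D, a cyclic AMP phosphodiesterase, 2.16-fold, and both were also higher in the non-silencing pair, by 0.54 and 0.61. CEACAM5, the carcinoembryonic antigen, rose 2.16-fold where the non-silencing pair differed by -0.91. Its vehicle replicates 1 and 2 read a dim 3.29 and 3.76, so that fold may also be a lower limit.

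Without the block, limma called 0 of 19774 genes for this response (547 at an unadjusted p under 0.05, smallest adjusted p 0.664). With the block, limma called 33 genes, 15 higher and 18 lower (1223 at an unadjusted p under 0.05), and with replicates 1 and 2 as one batch and all other arrays as the other, a term chosen after seeing the data, it called 49. On simulated data 9.01% of calls with the block were false, over the nominal 5%, so some of the 33 may be too. That simulation had pairing built in and noise independent between genes, so the share in the real data may differ. All 33 moved the same way in all 3 pairs, which a call in this fit nearly requires, so it adds no support. By the planned rule, the treated and untreated arrays did not overlap for 20 of the 33. The same held for 7.88% of all genes tested, where 10% is the share expected by chance. The batch term added 16 genes to the same 33; GATA6 itself (adjusted p = 0.0378), BMP4 (0.80), SOX4 (0.75) and PTCH1 (0.83) are among them. Within replicates 1 and 2 alone, 35 genes were called; replicate 3 has 1 array per treatment and gives no test of its own.

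**Figure D2:**
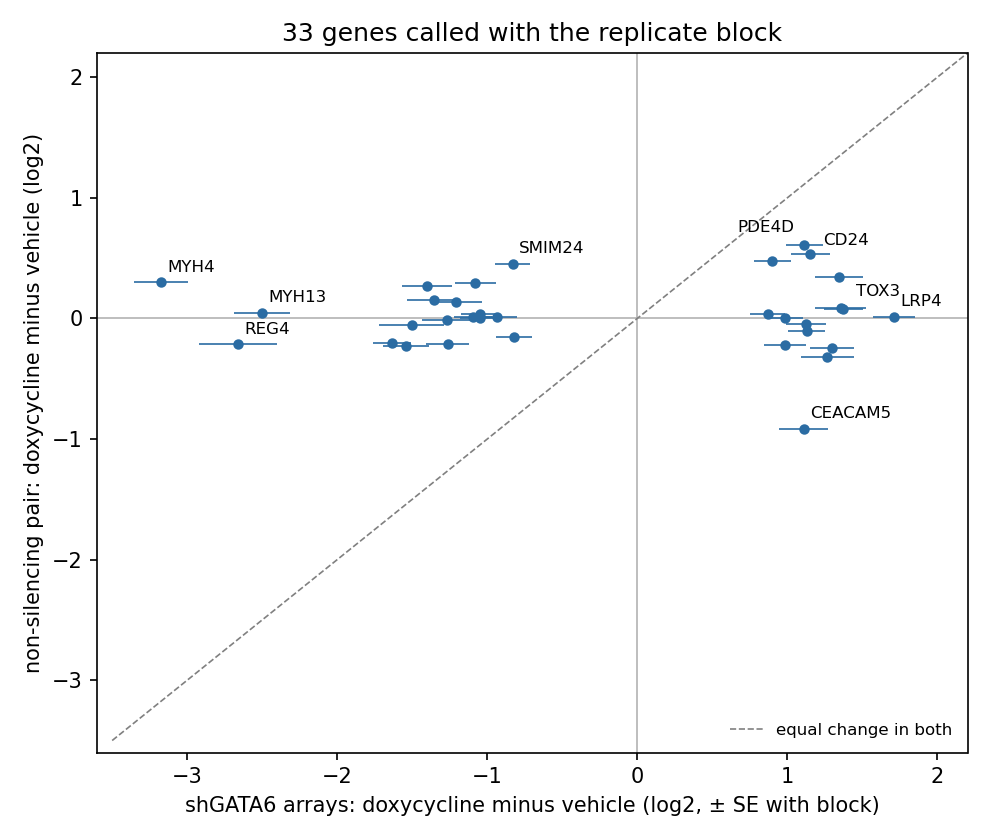
Change with doxycycline in shGATA6 cells (horizontal axis, log2, bars are the SE with the block, n = 3 pairs) against the change in the non-silencing pair (vertical axis, log2, 1 array each) for the 33 genes called with the block; the dashed line marks equal change. The shGATA6 changes range from -3.17 (MYH4) to 1.71 (LRP4), and the largest non-silencing difference is that of CEACAM5 (-0.91).

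Of the 27 measured Wnt and beta-catenin target genes, 21 were higher with doxycycline (median log2 0.09). With the block, EPHB3 rose and LGR5 fell over all genes; adjusted over the list alone, 8 rose and 1 fell. Those that rose on that basis included PROX1 (1.45 ± 0.25), NKD1 (0.91 ± 0.18), SOX4 (0.75 ± 0.13), APCDD1 (0.71 ± 0.17) and MYB (0.62 ± 0.12; log2 ± SE, n = 3 pairs). The common reporters AXIN2 (0.06 ± 0.12), MYC (-0.10 ± 0.13) and CCND1 (0.05 ± 0.12) did not pass. Camera called the list upward (adjusted p = 0.0146; adjusted p = 0.929 with an estimated correlation), and with the block adjusted p was 8.15e-07 (adjusted p = 0.742 with an estimated correlation). The call without the block was lost without vehicle replicate 1 (0.328), vehicle replicate 2 (0.323) or doxycycline replicate 3 (0.759), and without the last the list's mean turned from 0.23 to -0.0081. Leaving out 1 array of the fit without the block, here and below, unbalances treatment against replicate number. The difference between replicates then enters the change. With the block the list stayed called without pair 1 (0.00270), 2 (4.33e-09) or 3 (2.56e-05). The same list was lower on replicates 1 and 2 than on replicate 3 (median -0.39). Camera with an estimated correlation, here and below, rests on few residual degrees of freedom and can hardly pass. Its p therefore cannot tell whether correlation between genes made a call.

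Intestinal stem cell genes went both ways. Of 21 measured members, with the block LGR5 fell and EPHB3 rose over all genes; adjusted over the list alone, SMOC2 (0.95 ± 0.18) also rose and RGMB (-0.45 ± 0.12) fell. OLFM4 (0.04 ± 0.15) and ASCL2 (0.30 ± 0.14) did not pass, and camera did not call the list (adjusted p = 0.506, with the block 0.251). Without doxycycline replicate 3, SMOC2 read -0.07 and RGMB 0.04 in the fit without the block.

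BMP4 was higher by 0.80 ± 0.14 with doxycycline (log2 ± SE, n = 3 pairs), called with the block adjusted over the list alone and not over all genes (adjusted p = 0.0833). BMP2 (-0.28 ± 0.14) and BMP7 (-0.09 ± 0.13) did not pass, and the 27 measured BMP ligands, receptors and antagonists were not called as a list (adjusted p = 0.669, with the block 0.422). Among 16 measured BMP-SMAD response genes, 3 rose with the block adjusted over the list alone and 0 over all genes by limma: ATOH8 (0.59 ± 0.14), SMAD9 (0.55 ± 0.15) and ID3 (0.49 ± 0.14). ID1 (0.49 ± 0.17) did not pass and ID2 read -0.13 ± 0.18. Camera did not call this list without the block (adjusted p = 0.0858) and called it upward with it (adjusted p = 0.0364; adjusted p = 0.806 with an estimated correlation), a call lost without pair 1 or pair 2.

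Among genes of differentiated gut cells, those called went both ways, and in each list more members were lower than higher. Lower were 19 of 33 goblet and secretory, 24 of 33 absorptive colonocyte and 12 of 15 gastric and foregut genes. So were 5 of 9 Paneth cell and 11 of 20 enteroendocrine genes, with list medians from -0.06 to -0.0082. The median of all genes was itself -0.034. Those of the goblet (-0.029), Paneth (-0.027) and enteroendocrine (-0.0082) lists lay above it, so these counts alone show no fall particular to differentiated cells. Of 33 measured goblet and secretory genes REG4 was the one called over all genes with the block; adjusted over the list alone, 2 rose and 6 fell, SYTL2 (0.77 ± 0.13) among the former and AGR2 (-0.50 ± 0.12) and AGR3 (-0.48 ± 0.15) among the latter, while MUC2 (-0.08 ± 0.12) and TFF3 (0.26 ± 0.20) did not pass. Of 33 measured absorptive colonocyte genes CEACAM5 rose over all genes; adjusted over the list alone, FABP1 (-1.02 ± 0.17), LGALS4 (-0.49 ± 0.12) and CDHR5 (-0.42 ± 0.12) fell. Of the 15 gastric and foregut genes TFF1 fell by 0.79 and MUC5AC rose by 0.77 adjusted over the list alone, but in the fit without the block TFF1 read 0.04 without vehicle replicate 3 and MUC5AC -0.33 without doxycycline replicate 3. Of the 9 Paneth cell genes CD24 rose, and PLA2G2A (-0.85 ± 0.19) fell adjusted over the list alone but read 0.51 without vehicle replicate 3. None of these 4 lists was called by camera (adjusted p with the block 0.685, 0.256, 0.723 and 0.825), nor were the 20 enteroendocrine genes (0.627).

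Among the other lists, camera with the block called cell cycle genes upward (median 0.05, 24 of 38 higher, adjusted p = 0.0104; adjusted p = 0.806 with an estimated correlation) and interferon response genes downward (median -0.18, 24 of 31 lower, adjusted p = 0.0376; adjusted p = 0.806 with an estimated correlation). With the block the cell cycle call was lost without pair 2 or pair 3, and the interferon call without any 1 of the 3 pairs and with the mean of probe sets. In the fit without the block the cell cycle list's mean turned from 0.06 to -0.02, -0.05 and -0.16 without vehicle replicate 1, vehicle replicate 2 and doxycycline replicate 3. Neither was called without the block (0.235 and 0.288), and limma called 0 members of either with the block, over all genes or adjusted over the list alone; IFIT2 read -0.46 ± 0.13 and MCM2 0.17 ± 0.12. EREG rose among MAPK/ERK output genes and EGFR ligands, and adjusted over the list alone PHLDA1 (0.54 ± 0.15) rose and EPHA4 (-0.52 ± 0.12) fell among the former. HES6 (0.63 ± 0.15) rose among Notch pathway genes adjusted over the list alone. Of 8 GATA and FOG genes, GATA6 passed adjusted over the list alone, and GATA4 (-0.12 ± 0.13), GATA2 (0.05 ± 0.13) and GATA5 (-0.14 ± 0.13) did not. Of 20 gut transcription factors PROX1 rose adjusted over the list alone, and CDX2 (0.08 ± 0.14) and CDX1 (-0.20 ± 0.12) did not pass. Without the block GATA6, EREG, EPHA4, REG4 and SYTL2 also passed adjusted over their lists alone. Camera called none of these 5 lists (adjusted p with the block 0.685, 0.256, 0.256, 0.172 and 0.339). Markers of other cell types, fibroblasts, leukocytes and endothelium, were not called (adjusted p = 0.449, 0.980 and 0.773; with the block 0.380, 0.935 and 0.807), with EPCAM at 10.5 to 10.9 on all arrays and the leukocyte gene PTPRC at 2.28 to 2.58.

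The remaining lists were not called by camera in either fit and had 0 members called by limma with the block, over all genes or adjusted over the list alone, at an adjusted p under 0.05; their largest changes are given as values (log2). Stress genes DDIT3 and FGF21 read -0.53 and -0.46, and the hypoxia gene NDRG1 -0.62 and the glucose transporter SLC2A1 0.30. The p53 targets FAS and TP53INP1 read -0.29 and 0.30, and the kinase inhibitors CDKN1A and CDKN1C -0.26 and 0.53. Junction genes CLDN2 and CDH17 read -0.92 and -0.46, and mesenchymal genes TGFBI and TNC 0.49 and 0.52. Lipoxygenase and prostaglandin genes LTC4S and PTGER4 read -0.23 and -0.52, respiratory chain genes CYC1 and NDUFS8 -0.20 and -0.22, and cholesterol genes PMVK and STARD4 -0.30 and -0.39. The hormones CCK and SST read -0.23 and 0.23, ribosomal RPL13 and RPS9 both -0.09, reference genes IPO8 and TFRC 0.12 and 0.25, endothelial CDH5 and EMCN -0.13 and -0.17, fibroblast FAP and THY1 0.30 and -0.19, and leukocyte CD3D and CORO1A -0.25 and 0.28. From lists described above, the cell cycle gene GINS2 read 0.31, Notch ligand DLL4 0.64 and the gut factor FOXA1 0.38; DDIT3, FGF21, DLL4, TNC, GINS2 and others of these changed sign when 1 array was left out.

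The difference between the shGATA6 and the non-silencing response asked which changes go with the GATA6 hairpin. For GATA6 that difference was -1.39 ± 0.52 (log2 ± SE, 3 shGATA6 arrays per treatment against 1), for MYH4 -3.47 ± 1.55 and for MFSD2A 1.54 ± 0.31, as values that did not pass. By smallest p the upper end also held THSD4 (1.39 ± 0.24) and SYTL2 (1.37 ± 0.29), and the lower end CRNDE (-1.88 ± 0.22) and SEMA7A (-1.30 ± 0.20), whose shGATA6 changes were 0.0047 and -0.04. Both came from the lone non-silencing doxycycline array, where CRNDE read 3.86 and SEMA7A 4.28. All other arrays read at most 2.56 and 3.34, near the floor. Limma called 0 genes without the block (702 at an unadjusted p under 0.05) and 0 with it (1179); with the batch term it called MYH4 alone (adjusted p = 0.0490). With the block camera on this difference called the Wnt target list upward (adjusted p = 1.77e-04; adjusted p = 0.877 with an estimated correlation), on 1 non-silencing array per treatment; it was not called without the block (0.205).

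In the non-silencing cells, among genes with a mean over the median of all genes (4.59), the largest doxycycline differences were SOCS2-AS1 (1.02), SLC7A5P2 (1.01) and ABCB8 (1.00) upward, and GPALPP1 (-1.19), SLC25A18 (-1.03) and RAB3D (-0.96) downward (log2, 1 array against 1). These have no replicate check, and the test borrows the spread of the shGATA6 arrays. Limma called 0 genes (821 at an unadjusted p under 0.05), 0 with the block and 0 with the batch term.

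Between vehicle-treated shGATA6 and non-silencing cells, with the same limit on the mean, the largest differences included INHBE (3.43), SPINK1 (3.11) and NIBAN1 (2.63) higher and MUC5AC (-2.52), ASB4 (-2.51), PLA2G2A (-2.44), SMOC2 (-2.32) and CEACAM6 (-2.25) lower in shGATA6 cells (log2, 3 arrays against 1). These followed the replicate number: INHBE read 8.13, 8.09 and 3.72 on vehicle replicates 1, 2 and 3 against 3.22 on the non-silencing vehicle array, and MUC5AC 6.03, 6.39 and 10.3 against 10.1. With the batch term the difference was 0.56 for INHBE, -0.09 for NIBAN1, 0.02 for PLA2G2A and 0.68 for CEACAM6. Limma called 0 genes (754 at an unadjusted p under 0.05) and 0 with the batch term (842).

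Arrays stood apart by replicate number in both treatments. Replicates 1 and 2 correlated with each other, and replicate 3 with the non-silencing arrays, at 0.987 to 0.995, against 0.974 to 0.981 between these sets; the first principal component held 55.6% of the variance. With the batch term limma called 3449 genes between replicates 1 and 2 and replicate 3, 1816 higher and 1633 lower in the former. The sets were chosen from these same arrays, so the counts and p-values here describe a split already seen and do not test it. Vehicle and doxycycline arrays of one replicate number were counted as independent, and replicate 3 has 1 array per treatment. Genes of the integrated stress and unfolded protein response were higher on replicates 1 and 2 (median 1.03, 25 members called upward, adjusted p = 4.72e-16; adjusted p = 0.135 with an estimated correlation), among them DDIT4 (2.93), TRIB3 (2.48) and ASNS (1.92). Cell cycle genes were lower (median -0.73, 27 called downward, adjusted p = 3.62e-17; adjusted p = 0.135 with an estimated correlation), as were Wnt target genes (adjusted p = 4.66e-08; adjusted p = 0.135 with an estimated correlation) and stem cell genes (median -0.29, adjusted p = 1.32e-04; adjusted p = 0.489 with an estimated correlation), OLFM4 by 2.16 among the last.

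**Figure D3:**
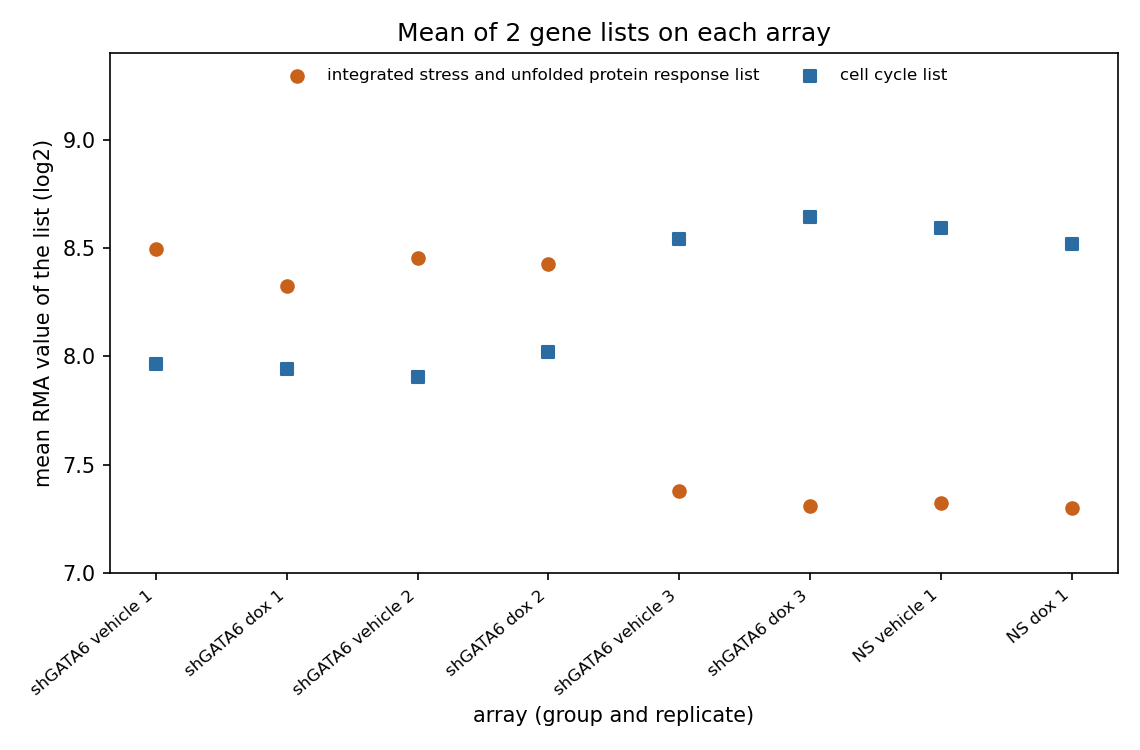
Mean RMA value (log2, vertical axis) of the integrated stress and unfolded protein response list (orange circles) and the cell cycle list (blue squares) on each of the 8 arrays (horizontal axis). The stress list lies between 8.32 and 8.49 on the 4 arrays of shGATA6 replicates 1 and 2 and between 7.30 and 7.38 on the other 4, and the cell cycle list between 7.91 and 8.02 and between 8.52 and 8.64.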

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

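The 2 counts of relabelled arrays were planned; the other tests here were chosen after the results were seen, and the criteria for doxycycline and RNA quality were revised after a first run of those tests. MYH4 was the gene whose response differed between the hairpins, by -3.47 in the fit with the batch term (adjusted p = 0.0490), and not in the fits without a block (1.00) or with it (0.0755). A probe set which the annotation used here does not name and which no comparison used was higher with doxycycline by 1.22 ± 0.13 with the block (adjusted p = 0.0424, higher in 3 of 3 pairs) and read 6.41 and 6.53 on the non-silencing arrays.

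Calls of the shGATA6 response numbered 0 without the block and 33 with it. The 10 splits of the 6 arrays into 3 and 3 all called 0 without the block (10 of 10 as many as the real split, highest other 0), and the 4 ways of swapping treatment within pairs called 33 for the real labels (1 of 4) and at most 0 for the others; both sets are too few for a share under 0.05. Doxycycline without the GATA6 hairpin predicts that the non-silencing pair moves the same 33 genes the same way. Their median change there, signed along the shGATA6 change, was -0.0070 (bootstrap interval over genes -0.05 to 0.06) against a median size of 1.21 in shGATA6 cells. That pair did not show the predicted change. The interval holds no spread between arrays, and the criterion asked for more than 1 non-silencing pair, so the test cannot decide. An effect of loss of GATA6 is therefore a hypothesis that stays open beside an effect of doxycycline alone. It also stays open beside an off-target effect of the hairpin, since no further hairpin was analysed here.

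Replicates 1 and 2 of both treatments stood apart from replicate 3 and the non-silencing arrays. Loss of RNA quality in one set predicts large differences on one side, and 45 genes were higher and 34 lower by over 2 log2 on replicates 1 and 2. RMA equalises the arrays, so a one-sided loss can also read as differences on both sides, and these counts cannot decide. The 3′ minus 5′ signals of the sets overlapped for actin (0.37 to 0.45 and 0.36 to 0.48) and for GAPDH (-0.39 to -0.11 and -0.43 to -0.28). That covers these control transcripts only. Background added to dim genes predicts no large difference among bright ones, although GC-rich control probes did read 5.84 to 6.36 against 4.26 to 5.10; 40 of 2402 genes with means over 8 in both sets differed by over 1 log2. The stress list differed by a median of 1.03 and the cell cycle list by -0.73, and vehicle replicate 3 differed from the non-silencing vehicle array by 0.08 and -0.03. These lists were known to differ before stressed, slower cycling cultures were tested with them. That explanation therefore stays open beside loss of RNA quality, a hybridisation batch or a different subculture, as the labels name none.

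Genes beside each other on a chromosome moved together. At an unadjusted p under 0.01 with the block, 366 genes held 23 neighbouring pairs of one direction (gene order from GRCh38.p14), against a mean of 3.58 and a highest of 13 in 10000 shuffles (permutation p = 0.0001, the smallest they can give). By symbol, 12 pairs were related. Shared probe sets could account for those of similar genes, such as MYH13 with MYH8, MYH8 with MYH4, and GSTM4 with GSTM2. Other related pairs join a gene and its divergent or antisense transcript, as for CEBPA and NR2F1, where sharing was not examined. The 11 pairs with unrelated symbols stood against a mean of 3.16 and a highest of 12 in the shuffles (permutation p = 0.001). They included MYCL with MFSD2A (0.80 and 1.30), RUNX2 with CLIC5 (1.22 and 0.72) and GAS7 with MYH13 (-0.66 and -2.50). As many genes of smallest p between the sets of arrays held 14 neighbouring pairs in all, 9 of them unrelated, so an excess is not particular to the GATA6 hairpin. Regulation of neighbouring genes together is a hypothesis here, and no biological explanation was tested.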

How the results depend on the processing

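Batch-term, replicates-1-and-2 and with-block alternatives were chosen after seeing the data, except the replicate block itself. The shGATA6 response (0 genes called by limma, 547 at an unadjusted p under 0.05) moved to 33 with the replicate block, 49 with the batch term and 35 on replicates 1 and 2 alone, and kept 0 under every other setting, each array left out included. The difference between hairpins moved from 0 to 1 with the batch term, and the non-silencing response from 0 to 1 with trend and robust priors and to 1 with array weights. With the block the count of 33 moved to 64 with dim genes under the median left out (fewer genes tested), 80 with trend and robust priors, 53 with array weights and 7 at an adjusted p under 0.01. The mean of probe sets called 23, with 19 of the 33 kept, and testing every probe set called 29, with 13 of the 33 kept. Without pairs 1, 2 and 3 it was 32, 27 and 48, of which 22, 24 and 30 are among the 33. Lists called moved from 1 to 2 with genes under the median left out (1 with the lowest 25% left out), 2 with the mean of probe sets, 3 with array weights, 4 with the replicate block, 4 with the batch term, 2 on replicates 1 and 2, 0 with an estimated correlation, 0 with fry, 0 on the hairpin difference, and 0 to 5 with 1 array left out. With the block the 4 lists moved to 0 with an estimated correlation, 0 with fry, 1 on the hairpin difference, and 1 to 3 without 1 pair. With an estimated correlation camera has few residual degrees of freedom, so those counts cannot tell whether correlation between genes made the calls. GATA6 read -1.18 in every fit of all arrays on the deposited values except with array weights (-1.09) or the mean of its probe sets (-1.34), passed with the batch term alone (-1.18), and ranged from -1.39 to -0.88 with 1 array left out. With the replicate block the counts of the hairpin difference and the non-silencing response stayed at 0. Directions turned as follows. With 1 array left out of the fit without the block, treatment is no longer balanced over the replicate numbers. The difference between replicates then enters the change, so those turns do not measure the response alone. Other causes were not tested. In the vehicle baseline the batch term gave CEACAM6 0.68, NIBAN1 -0.094 and PLA2G2A 0.025. On replicates 1 and 2 alone LTC4S read 0.022, TGFBI -0.048 and TNC -0.024, on the shGATA6 arrays alone CDKN1C -0.053, and with the mean of probe sets EMCN 0.0051. With 1 array left out, mostly a replicate 3, values without the block ranged across 0, from -0.0081 to 0.44 for the Wnt list mean and -0.16 to 0.26 for the cell cycle list mean, and for CDH5 from -0.28 to 0.011, CDKN1C -0.0034 to 0.82, DDIT3 -1.31 to 0.30, DLL4 -0.10 to 1.03, FAS -0.56 to 0.012, FGF21 -1.41 to 0.47, FOXA1 -0.026 to 0.64, GINS2 -0.10 to 0.75, MTCL1 -0.023 to 1.40, MUC5AC -0.33 to 2.15, PLA2G2A -1.96 to 0.51, PTGER4 -1.28 to 0.18, RGMB -0.92 to 0.040, SMOC2 -0.065 to 2.17, SPINK1 -2.34 to 0.50, TFF1 -1.81 to 0.036, TFRC -0.075 to 0.58 and TNC -0.22 to 0.94. Of the single values in the fit without the block 2217 alternatives kept direction and side of the threshold, 126 passed it and 4 lost it. With the block 402 kept both, 77 lost the threshold and 0 turned. Signals near the floor limit what arrays resolve, as for MYH1, MYH2 and MYH3.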

Other observations

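Myosin genes that fell with doxycycline in shGATA6 cells lie in one cluster of skeletal muscle heavy chains. Both probe sets of MYH8 were lower with the block, at -1.11 ± 0.14 and -0.87 ± 0.13 (log2 ± SE, adjusted p over probe sets 0.0573 and 0.140), and MYH1 (-0.33 ± 0.13), MYH2 (-0.28 ± 0.11) and MYH3 (-0.44 ± 0.14) lay near the floor, with vehicle means of 2.73, 3.49 and 3.39. No probe set of the non-muscle genes MYH9 (-0.0079 ± 0.12), MYH10 (-0.0067 and -0.069) and MYH14 (from -0.39 to -0.076), the smooth muscle gene MYH11 (from -0.29 to 0.081) or the cardiac gene MYH7 (-0.36 ± 0.11) passed either. The MYH10 probe sets (vehicle means 3.42 and 3.23) and some of MYH11 (2.71, 3.16 and 3.19) also lay near the floor. Their lack of change is therefore little evidence. The myosin genes given here were chosen after their values were seen.

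Across all 19774 genes the 3 shGATA6 pairs shared little of their doxycycline change. The correlation across genes, which are not independent replicates, was 0.19 for pairs 1 and 2, -0.07 for pairs 1 and 3 and 0.16 for pairs 2 and 3, against 0.12, 0.0096 and -0.11 of each pair with the non-silencing pair. GATA6, by the probe set that represents it, differed by -0.65, -1.18 and -1.71 in pairs 1, 2 and 3. In the same order its other probe set read 7.50, 7.65 and 7.09 with vehicle and 6.08, 6.39 and 5.30 with doxycycline. That fall was smallest in pair 2, so the probe sets did not rank the pairs alike.

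Of the mu class glutathione transferases GSTM1 and GSTM4 passed over all genes with the block. As values, GSTM2 read -0.98 ± 0.17, the 2 probe sets of GSTM3 -0.53 ± 0.13 and -0.014 ± 0.12, and GSTM5 -0.11 ± 0.15. Among neighbouring genes, as values that did not pass with the block, CEBPA, a transcription factor of epithelial differentiation, and its divergent transcript differed by -0.58 and -0.51, and NR2F1 and its antisense RNA by 0.77 and 0.71; the last passed with the batch term (adjusted p = 0.0378).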
